A study of Mus musculus with 8 samples.

How the data were processed

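Total RNA from mouse bone marrow-derived macrophages was measured on 8 Affymetrix arrays, 1 array for each of 8 groups. Per the labels' protocols, bone marrow of C57BL/6 mice was cultured for 7 days with 10% serum and M-CSF, the growth factor that drives marrow cells to become macrophages. Cells were then plated and harvested 24 h later without stimulus or after 6 h or 24 h with 1 µg/ml of smooth lipopolysaccharide (LPS), a bacterial outer membrane component. Wild-type and CD14-deficient cells were used. EGTA, a chelator that binds calcium outside the cell, was added to wild-type cells with LPS. Its concentration, 2 mM, is given in the label of the 24 h sample and not in that of the 6 h sample. Each labelling reaction started from 0.3 µg of RNA. RNA integrity numbers ran from 9.3 to 9.7. The yield of labelled cRNA ran from 31.4 µg, for EGTA at 24 h, to 76 µg, for wild type with LPS at 6 h.

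The deposited values are linear intensities, 1 for each of 22690 probe sets on each array. The authors made them with MAS5, per the submitters' processing notes, which name no version. Whether the arrays were scaled to a common target is not given in the sources used here, and neither are detection calls. The 2% trimmed means of the deposited intensities ran from 314 for EGTA at 6 h to 527 for wild type with LPS at 6 h, a ratio of 1.68. The geometric means of spiked-in control probe sets went the other way, at 2214 and 1997 on these arrays. The rule set before the data were examined was to keep the deposited intensities where trimmed means agreed within 10% and to quantile normalize them otherwise, so they were quantile normalized over the 8 arrays. Quantile normalization gives all arrays 1 distribution and so removes any true shift of all genes together. Values below the 40th percentile of all values, an intensity of 38.4, were raised to it as a floor, and log2 was taken. A difference with 1 array at the floor is a bound and is given as "at least". A fold over a dim value just above the floor is imprecise, since no detection calls are at hand. No order is read among values at the floor.

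Probe sets were named through the platform annotation, with symbols updated by gene identifier from a RefSeq gene table of assembly GRCm38.p6. Of the probe sets, 20393 had 1 gene, 691 had several and were not used, 1606 were not listed and stayed unnamed, and 64 of the latter were array controls. Of the 20393, 20364 matched by gene identifier. They covered 12393 genes, 4956 of them with over 1 probe set. Each gene was represented by its probe set with the highest mean log2 over the 8 arrays. The array build is not given in the sources used here, so no coordinates are printed.

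In each of 9 comparisons of 1 array with 1 array, a gene was compared if its brighter array exceeded the median of all values, an intensity of 88.2. The log2 difference was taken, and genes at least 2-fold higher or lower were counted. No group has a replicate, so none of these differences has a replicate check and no p-value is given for them. The number of arrays limits the precision. Gene lists fixed before the data were examined, 30 in number with 490 genes, were described by their counts and their median. The median was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. Lists with at least 5 compared genes received such a placing, and 54 of the 490 genes were not analysed here. Genes of a list are co-regulated, so an extreme placing is easily reached and describes these arrays only.

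Named genes followed a rule also set beforehand. They were the 10 largest increases and 10 largest decreases with both arrays above the floor, the 3 largest differences in each list, and a fixed set of Cd14, Tnf, Il6, Il12b, Il10, Ifnb1, Cxcl10, Il2, Rcan1, Csf2, Ptgs2 and Ptges. For genes shared by EGTA and CD14 deficiency they were the 10 with the largest smaller difference. Genes named outside the rule are marked as chosen after their values were seen.

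The effects of EGTA and of CD14 deficiency are both measured against the wild-type LPS array. Their overlap was set beside that of independent lists, beside 200 simulations of unchanged groups against 1 shared array, with the scatter of the EGTA pair at 6 h for both times and, added after the data were seen, that of the 24 h pair for 24 h, and beside comparisons that share no array. A limma fit of all 8 arrays with additive terms for time and condition gave the effect of CD14 deficiency averaged over 0, 6 and 24 h and that of EGTA averaged over 6 and 24 h, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Its 3 residual degrees of freedom measure departure from additivity across times, not spread between cultures. Other splits of the 6 arrays without EGTA were fitted in the same way.

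The procedures were tested on simulated data. For EGTA at 6 h, over 6679 genes, 94% of 50 genes simulated at a log2 difference of 1.5 and 100% of 50 at 2 were called at least 2-fold different, as were 7 of 6479 unchanged genes. The changed genes were drawn from bright genes only, so recovery of dim genes was not tested. The same Gaussian scatter was used at every intensity, and the false calls hold for that scatter alone. Of 50 random lists of 20 genes with no shift, 2 lay outside the central 95% of random lists, and all 50 with a shift of 0.5 did. For the additive fit over 7291 genes, 68% of 50 genes with a simulated CD14 effect of 1 and 100% of those with 2 were called, with 13 false calls.

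The alternatives were the intensities as deposited, an equal median over probe sets above the floor, a floor at the 20th percentile or none, a filter at the 75th percentile or none, a 3-fold threshold and the mean of all probe sets of a gene. For the additive fit they also included leaving out each time and an intensity trend with robust variances. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.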

Results

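Expression was measured in bone marrow-derived macrophages of wild-type and CD14-deficient mice before and 6 h and 24 h after LPS, and in wild-type macrophages given LPS together with EGTA for 6 h or 24 h. CD14 is a surface protein that hands LPS to its receptor, the TLR4 complex. According to the series' design text and title, the comparison of these conditions was meant to single out effects of calcium influx and of NFAT, a calcium-activated transcription factor, from other effects of CD14 loss and of EGTA. There was 1 array per group, so every difference between a pair of arrays below is a single observation with no replicate check. No array held EGTA without LPS.

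Cd14 itself matched the labels. Its intensity was 3849 in unstimulated wild-type cells, 12515 after 6 h of LPS and 8564 after 24 h. In all 3 arrays labelled CD14-deficient it was at the floor of 38.4, at least 100.3-fold, 326-fold and 223-fold lower than in wild type at 0, 6 and 24 h. Whether the probe set lies in the deleted part of the gene is not given in the sources used here. With EGTA it stood at 11088 and 5998 at 6 and 24 h. The ratios of 3' to 5' actin probe sets ran from 1.11 to 1.27 and those of Gapdh from 0.69 to 0.80.

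**Figure D1:**
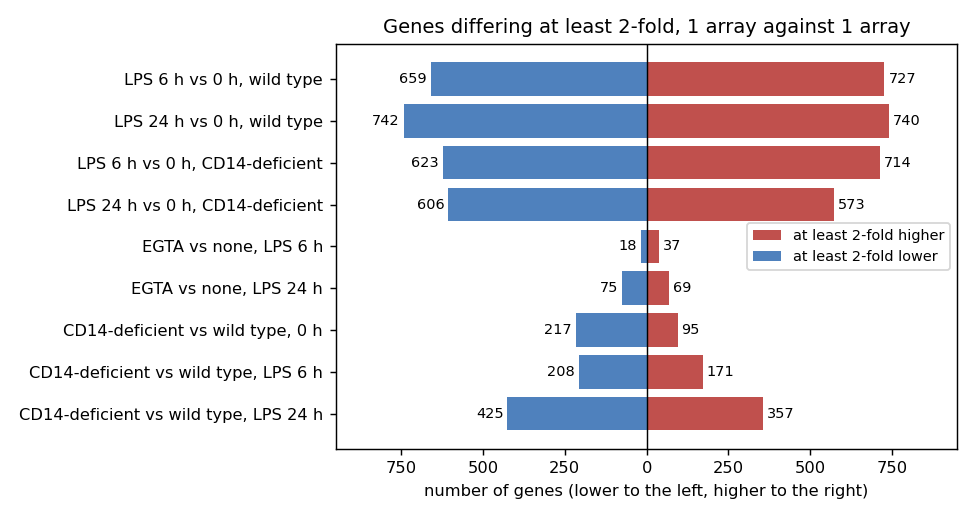
Number of genes at least 2-fold higher (red, to the right) or lower (blue, to the left) in each of 9 comparisons of 1 array with 1 array, after quantile normalization. LPS separated 573 to 740 genes upward, EGTA 37 and 69, and CD14 deficiency 95 to 357. With the intensities as deposited the EGTA counts at 6 h turn to 2 higher and 1353 lower.

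In wild-type macrophages, 6 h of LPS gave high levels of cytokine, chemokine and costimulatory genes. Cd40, a costimulatory receptor, was 82.8-fold higher, the chemokine genes Cxcl11 and Cxcl10 were 57.7-fold and 28.0-fold higher, and Il1b was 44.3-fold higher. Il6 and Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, were at the floor before LPS and at least 40.1-fold and 42.0-fold higher after it. Tnf was 11.9-fold higher, Il10 24.0-fold, Il12b at least 7.99-fold and Ifnb1 at least 5.57-fold. Of 21 inflammatory cytokine and NF-kB target genes compared, 17 were at least 2-fold higher and none lower, with a median log2 difference of 2.92. Of 28 type I interferon response genes, 21 were higher, with a median of 2.33. Feedback inhibitors of LPS signalling were higher in 10 of 15 and lower in 1, among them Socs3 (18.8-fold) and Tnfaip3 (8.50-fold). All 3 medians lay above those of all 10000 random lists. Rcan1, a calcineurin inhibitor that NFAT induces, was 3.68-fold higher, and 4 of 6 calcineurin-NFAT target genes were higher and 1 lower, while Il2 and Csf2 were at the floor on all 8 arrays.

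Among genes lower after 6 h were Sesn1 (20.7-fold), the mRNA decay factor gene Zfp36l1 (11.9-fold), the phosphatase gene Dusp6 (11.5-fold), the iron exporter gene Slc40a1 (9.72-fold) and the immediate early gene Egr1 (9.66-fold). Of 13 immediate early genes 6 were at least 2-fold lower and 2 higher. Glycolysis and hypoxia genes were higher in 7 of 17, led by Pfkfb3 (7.54-fold) and including the glucose transporter gene Slc2a1 (2.68-fold). Over 6935 genes, 727 were at least 2-fold higher and 659 lower.

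After 24 h of LPS, wild-type cells kept high levels of Cxcl11 (93.9-fold), Il1b (53.4-fold), Saa3 (37.6-fold), an acute-phase gene, and Ptges (39.2-fold), which encodes the enzyme that makes prostaglandin E. The complement factor gene Cfb was 44.8-fold and the formyl peptide receptor gene Fpr2 50.4-fold higher. Tnf was 11.1-fold higher, and Il6 at least 21.3-fold, the log2 difference of Il10 was 3.58, and Rcan1 was 1.26-fold higher. Antigen presentation and costimulation genes were at least 2-fold higher in 10 of 18, with Tap2 at 5.88-fold and Cd86 at 5.69-fold, against 6 of 18 at 6 h. Cell cycle genes were at least 2-fold lower in 18 of 23, with a median of -1.37 that lay below all 10000 random lists, and Rrm2, Cdc20 and Bub1 were 7.03-fold, 6.49-fold and 6.36-fold lower. Cholesterol synthesis genes had a median of -0.66, below that of 9989 of 10000 random lists, with Dhcr7 and Sqle 3.79-fold and 3.56-fold lower. Over 6964 genes, 740 were higher and 742 lower. With intensities as deposited these counts were 365 and 2199, and the median of all compared genes lay at -0.66 in place of -0.07.

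CD14-deficient macrophages responded to LPS with large differences from their own unstimulated array. At 6 h the acute-phase gene Saa3 was 344-fold higher, Il1b 310-fold, the interferon-induced gene Ifit1 164-fold and Cd40 143-fold, and Cxcl10 and Ccl5 were at least 337-fold and 307-fold higher. The unstimulated intensities of Saa3, Il1b and Cd40, 42.8, 42.1 and 57.1, lay close to the floor, so their folds are imprecise. Tnf was 55.1-fold higher and Il6 at least 65.4-fold. Ifnb1 reached an intensity of 66.8, below the level at which genes were compared. All 27 interferon response genes compared were at least 2-fold higher, with a median log2 difference of 5.41, and 17 of 21 inflammatory genes were higher, with a median of 4.18. At 24 h Saa3 was 332-fold, Ms4a4c 214-fold and Il1b 201-fold higher, and Marco, a scavenger receptor gene at the floor in unstimulated cells, was at least 56.2-fold higher. Il10 was 2.07-fold higher and Il6 at least 3.41-fold. All 23 cell cycle genes were at least 2-fold lower at 24 h, with a median of -2.88.

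The genotypes shared many LPS-responsive genes. At 6 h, 714 genes were higher and 623 lower of 6928 in CD14-deficient cells, and 573 higher and 606 lower of 6907 at 24 h. Over the 7090 genes compared in either genotype at 6 h, 728 were higher in wild type, 717 in CD14-deficient cells and 482 in both, against 73.6 for independent lists. Over the 7140 at 24 h, 742, 583 and 400 were higher, against 60.6. The responses of the genotypes have no array in common. The interferon response genes had a larger log2 response in CD14-deficient cells in 25 of 28 at 6 h, beside their lower unstimulated level given below. As deposited, the CD14-deficient counts were 495 higher and 1412 lower at 6 h and 474 and 832 at 24 h.

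With EGTA at 6 h of LPS few genes differed at least 2-fold. Of 730 genes that LPS had induced at least 2-fold in wild type, 5 were lower with EGTA and 2 higher, but with induction taken from the CD14-deficient arrays, which are not part of the EGTA difference, 2 of 696 were lower and 6 higher. Of 6739 genes, 37 were at least 2-fold higher and 18 lower, and the central 95% of genes lay between -0.58 and 0.60 in log2. The chemokine receptor gene Cxcr4 was 3.68-fold higher, the phosphatase gene Dusp2 3.22-fold and Acp5 2.97-fold. Genes of the endoplasmic reticulum stress response, which restores protein folding, had a median of 0.50, above all 10000 random lists, although with intensities as deposited their median was -0.11 beside a median of -0.78 over all genes. Of 21 members compared 6 were at least 2-fold higher and none lower, or 0 and 1 as deposited, among them Herpud1 (3.24-fold), Creld2 (2.80-fold) and Manf (2.77-fold). Lower were Wasl (3.29-fold), the oxidised lipoprotein receptor gene Olr1 (3.07-fold), the growth factor signalling inhibitor gene Spry2 (2.68-fold), Ell2 (2.23-fold) and Rgcc (2.28-fold).

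None of 28 interferon response genes and none of 21 inflammatory genes differed at least 2-fold with EGTA at 6 h. The median of the interferon genes was 0.03, within the central 95% of random lists. It was 0.40 with equal medians and -0.41 as deposited, or 0.37 above the median of all genes, and under both of these scalings it lay above all 10000 random lists. The median of the inflammatory genes was -0.16, below 9979 of 10000 random lists. As deposited the inflammatory median was -0.89 and 7 of 21 were at least 2-fold lower, beside the median of -0.78 over all genes. Log2 differences were -0.16 for Tnf, -0.65 for Il6, 0.04 for Il12b, -0.23 for Il10, -0.03 for Ifnb1 and -0.05 for Cxcl10. Of 6 calcineurin-NFAT target genes compared none differed at least 2-fold, and their median was -0.38, beside -0.16 for the inflammatory genes. A median of 6 genes is imprecise, so these medians are not ranked. The 6 members ranged from -0.65 to 0.30. Of the lower ones, Egr2 (-0.64) and Nfatc1 (-0.32) also stood lower after 6 h of LPS in wild type, at -1.56 and -0.67. Gadd45b and Ikzf1 went the other way with EGTA, at 0.12 and 0.30. Rcan1 stood at -0.65, Ptgs2 at -0.50 and Ptges at -0.44. As deposited, EGTA gave 2 higher and 1353 lower genes at 6 h, and with equal medians 35 and 18. The split thus rests on whether the arrays are normalized to each other.

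At 24 h EGTA gave 69 higher and 75 lower genes of 6753. Cxcr4 was 6.46-fold higher, the transporter gene Abcg3 4.23-fold and the kinase gene Sgk1 3.10-fold. Cholesterol synthesis genes were at least 2-fold higher in 9 of 14 and lower in none, with a median of 1.10 above all 10000 random lists. Against the CD14-deficient array at 24 h of LPS in place of the wild-type one the median was 0.11, above 8129 of 10000, and with EGTA at 6 h it was -0.02, or 0.05 with equal medians. Idi1, Dhcr7 and Mvd, enzymes of that pathway, were 3.10-fold, 2.84-fold and 2.82-fold higher, and the fatty acid enzyme genes Scd2 and Fasn 2.84-fold and 2.76-fold. Endoplasmic reticulum stress genes had a median of 0.42, with 3 of 22 at least 2-fold higher, namely Chac1 (at least 2.90-fold), Asns (2.44-fold) and Trib3 (2.19-fold).

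Lower with EGTA at 24 h were Serpinb2 (7.83-fold), a plasminogen activator inhibitor gene, the metallothionein genes Mt2 (2.75-fold) and Mt1 (2.17-fold), Ptges (2.45-fold), Timp1 (2.37-fold), Il6 (2.33-fold) and the neutrophil chemoattractant gene Cxcl1 (2.24-fold). Of 744 genes that LPS had induced in wild type at 24 h, 22 were lower with EGTA and 6 higher, or 12 and 6 of 567 with induction taken from the CD14-deficient arrays. Inflammatory genes had a median of -0.33, below all 10000 random lists, with 2 of 20 at least 2-fold lower, and interferon response genes had a median of -0.04 with none of 28 at least 2-fold different. Their median was -0.16 with equal medians and 0.01 as deposited, or -0.14 relative to all genes, low under both but within the central 95% of random lists. Cell cycle genes had a median of -0.59, with 1 of 17 at least 2-fold lower, and Plk4, a centriole kinase gene outside the list, was 2.64-fold lower. Rcan1 stood at -0.12, Ptgs2 at -0.76 and Tnf at -0.50. Of the calcineurin-NFAT target genes compared, Ptges lay lowest at -1.29, and the others lay between -0.14 and 0.37. This sample had the lowest cRNA yield of the 8, 31.4 µg. As deposited, 115 genes were higher and 42 lower.

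**Figure D2:**
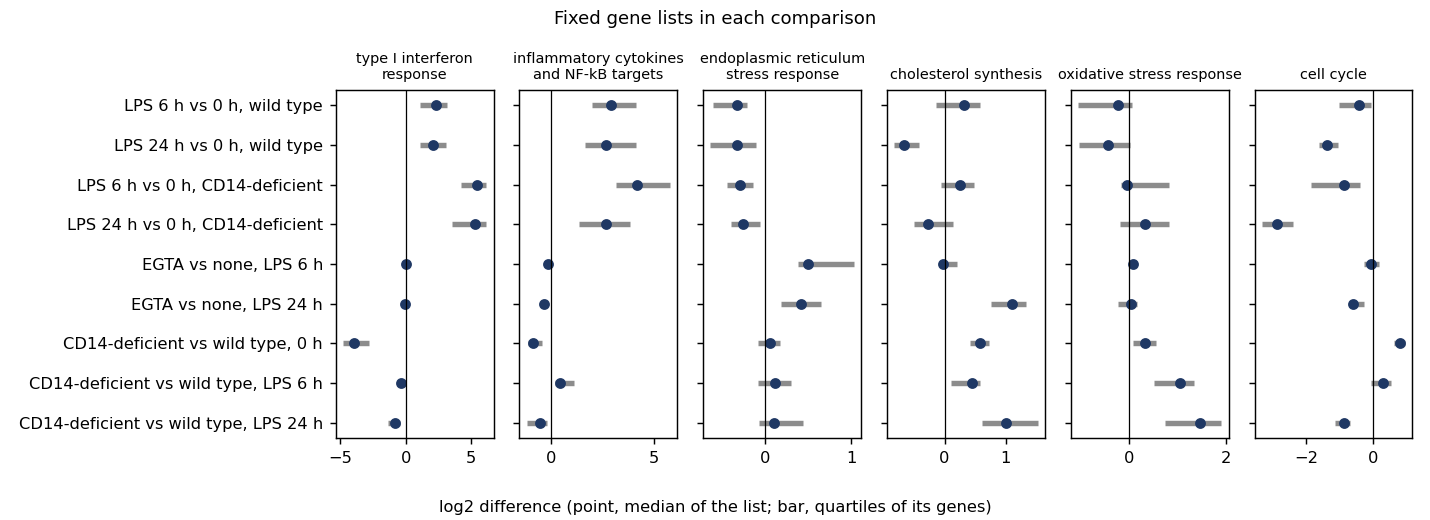
Median log2 difference (point) and quartiles (bar) of 6 fixed gene lists, 1 panel per list with its own scale, in each of the 9 comparisons. Interferon response genes lie at -3.94 in unstimulated CD14-deficient against wild-type cells, endoplasmic reticulum stress genes at 0.50 with EGTA at 6 h (-0.11 as deposited), and cholesterol synthesis genes at 1.10 with EGTA at 24 h.

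Before LPS, CD14-deficient macrophages had far lower levels of interferon-induced genes than wild type. Of 25 interferon response genes compared, 24 were at least 2-fold lower and none higher, with a median log2 difference of -3.94, below all 10000 random lists. Ifit3, Ifit1 and Ifit2, antiviral genes, were lower by log2 differences of -5.46, -5.32 and -5.29, the transcription factor gene Irf7 was 32.6-fold lower and the chemokine gene Ccl5 at least 197-fold lower. Ifit1 had an intensity of 2704 in the unstimulated wild-type array and 67.5 in the CD14-deficient one, while Ifnb1 was at the floor in both. Antigen presentation genes were lower in 12 of 17, with Cd86 9.91-fold, Cd74 5.61-fold and H2-Eb1 4.87-fold lower. Inflammatory genes were lower in 6 of 16, with Saa3 9.88-fold and Tnf 2.15-fold lower.

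Higher in unstimulated CD14-deficient cells were Gdf3 (9.19-fold), Ak4 (5.84-fold), Sox4 (4.42-fold) and Bnip3 (3.21-fold). Glycolysis and hypoxia genes were higher in 6 of 18 with a median of 0.45, including Egln3 (at least 4.71-fold), which encodes an oxygen-sensing hydroxylase, and Pdk1 (2.67-fold). Cell cycle genes were higher in 5 of 23 with a median of 0.81, among them Mki67 (2.47-fold) and Rrm2 (2.21-fold). Over 6781 genes, 95 were higher and 217 lower.

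**Figure D3:**
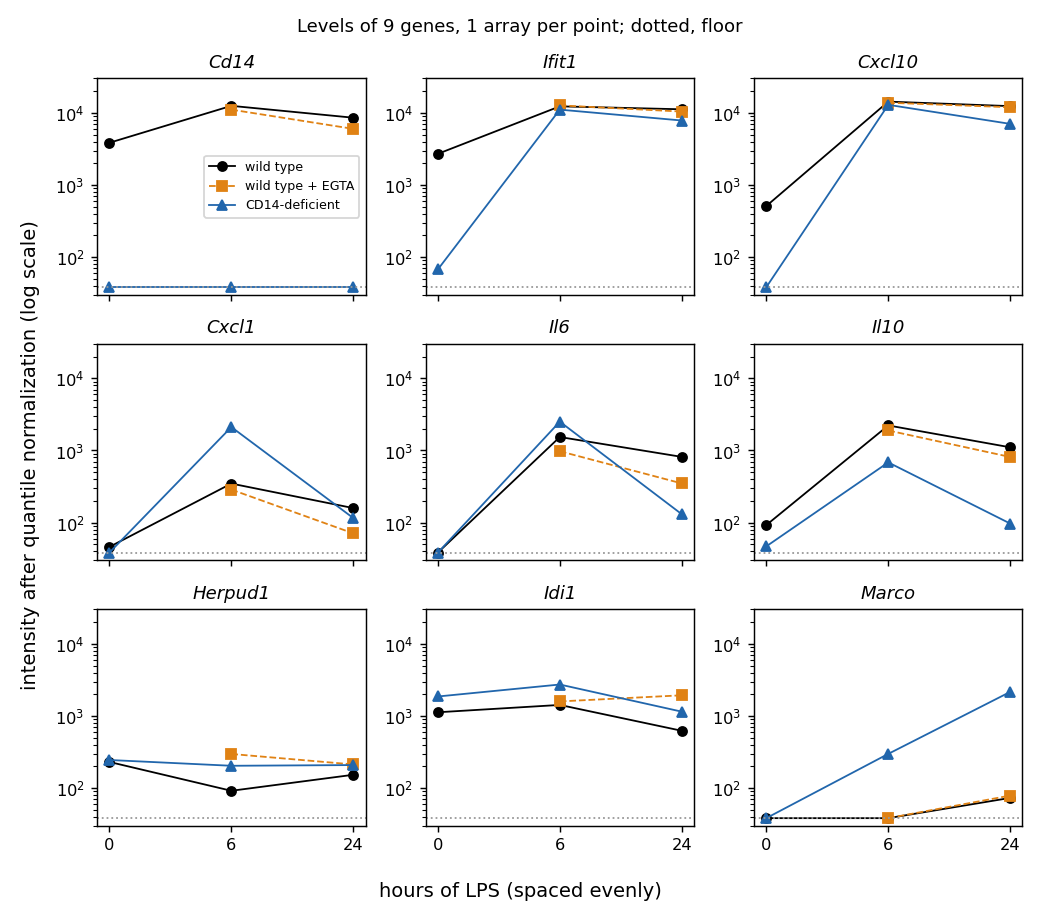
Intensity after quantile normalization (log axis) of 9 genes in wild-type cells (black circles), wild-type cells with EGTA (orange squares) and CD14-deficient cells (blue triangles) at 0, 6 and 24 h of LPS, 1 array per point, with the floor of 38.4 dotted. Cd14 is at the floor in the CD14-deficient arrays, Ifit1 starts at 2704 in wild type and 67.5 in CD14-deficient cells, and Marco ends at 2158 in CD14-deficient cells.

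After 6 h of LPS, several chemokine and cytokine genes were higher in CD14-deficient cells than in wild type. The neutrophil chemoattractant genes Cxcl1 and Cxcl2 were 6.07-fold and 5.69-fold higher, Il1a 4.99-fold, Tnf 2.16-fold and Il12b 2.04-fold. Of 21 inflammatory genes 7 were at least 2-fold higher and none lower, with a median of 0.44 above all 10000 random lists, and 4 were higher and 2 lower as deposited. Interferon response genes had a median of -0.36, below all 10000, with 5 of 28 at least 2-fold lower, and Cxcl9, Cxcl11 and Ifnb1 were 9.10-fold, 5.38-fold and 3.20-fold lower. Il10 was 3.25-fold lower, Cd86 6.39-fold and Il33 16.7-fold. Il6 stood at 0.71, Cxcl10 at -0.15 and Ptgs2 at 0.24. Of the calcineurin-NFAT target genes Egr2 and Ptges were higher, at 1.47 and 1.29. The other members compared lay between -0.50 and 0.00, with Rcan1 at -0.33.

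Oxidative stress genes were at least 2-fold higher in 6 of 10 at 6 h, with a median of 1.06. The cystine transporter gene Slc7a11 was 7.46-fold higher, Hmox1, which encodes a heme-degrading enzyme, 2.64-fold and Gclm 2.56-fold. The cholesterol efflux genes Abca1 and Apoe were 2.37-fold and 2.23-fold higher. Of 772 genes that LPS had induced in wild-type cells given EGTA, which are not part of this comparison, 136 were at least 2-fold lower in CD14-deficient cells and 25 higher, and of 566 that it had repressed there, 10 were lower and 49 higher. Those cells are wild type too, so choosing genes by their response may itself favour a smaller response in CD14-deficient cells. By each genotype's own arrays, 717 genes were higher after LPS in CD14-deficient cells and 728 in wild type. Over 6760 genes, 171 were higher and 208 lower, or 99 and 447 as deposited. Adi1, listed at 6.27-fold higher, had another probe set at -2.22.

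At 24 h of LPS the genotypes differed most in number of genes, with 357 higher and 425 lower of 6845. Marco was 29.5-fold higher in CD14-deficient cells, and the lipid synthesis genes Scd2 and Fasn were 10.7-fold and 6.02-fold higher. Oxidative stress genes were higher in 7 of 10 with a median of 1.47, led by Slc7a11 (at least 5.07-fold), Gclc (4.15-fold) and Gclm (3.84-fold). Cholesterol synthesis genes were higher in 7 of 14, or 11 as deposited, with a median of 1.00, with Dhcr7 at 4.03-fold, and glycolysis genes were higher in 8 of 18 and lower in 1, with Pdk1 at 3.69-fold and Pfkl at 3.14-fold. Il12b was 3.71-fold higher.

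Lower in CD14-deficient cells at 24 h were Cxcl11 (15.9-fold), Il10 (11.4-fold), Cxcl9 (11.2-fold), Cd86 (8.44-fold), the inducible nitric oxide synthase gene Nos2 (7.99-fold), Il6 (6.23-fold) and Ptgs2 (5.37-fold). Ifnb1 was at least 5.85-fold lower, while Tnf stood at -0.58. Inflammatory genes were lower in 7 of 21 and higher in 1, with a median of -0.54 (-0.24 as deposited and -0.74 with equal medians), and interferon response genes were lower in 9 of 28, with a median of -0.78, or in 18 with a median of -1.17 when the arrays were scaled to equal medians. Feedback inhibitors were lower in 7 of 16, including Socs1 (3.60-fold) and Tnfaip3 (3.51-fold). Of 6 calcineurin-NFAT target genes 2 were lower, with a median of -0.65, and Rcan1 stood at -0.65. Egr2, lower here at -1.51, had been higher at 6 h. Of 737 genes that LPS had induced in wild-type cells given EGTA, 249 were lower and 22 higher, and of 707 repressed there, 28 were lower and 182 higher. As at 6 h, this choice by wild-type cells may itself favour a smaller response in CD14-deficient cells. As deposited, 1089 genes were higher and 215 lower, and the median of all compared genes was 0.43.

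Genes that differed the same way with EGTA and with CD14 deficiency are those the design was meant to single out. Calcium was not measured here, so a shared difference cannot be told apart from other effects of EGTA and of CD14 loss. At 6 h, 3 genes were at least 2-fold lower in both, namely Rgcc, a cell cycle regulator gene, Efcab7 and Zfp777, of which 2 were also at least 2-fold higher after LPS in wild type, or 0 with induction required in the CD14-deficient and the EGTA arrays instead. Independent lists would share 0.56, and unchanged groups against 1 shared array shared 5.03 on average in simulation. The genes higher in both were Zap70, Cebpa, Sgk1, Herpud1 and Plod2, 5 in number, beside 0.48 for independent lists and 4.5 in simulation. Rgcc was 2.28-fold lower with EGTA and at the floor in all CD14-deficient arrays. As deposited 133 genes were lower and 1 higher in both.

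At 24 h, 24 genes were lower in both, beside 4.78 for independent lists and 4.55 in simulation with the 6 h scatter, or 9.69 and at most 18 with that of the 24 h EGTA pair, and 15 of them were induced by LPS in wild type, or 6 with induction required in the CD14-deficient and the EGTA arrays instead, which are those that lie lower. They included Serpinb2 (-2.97 with EGTA and -2.03 with CD14 deficiency), Serpinb1a, the growth factor gene Pgf, Timp1, Mxd1 and Il6 (-1.22 and -2.64). Of the 20 genes higher in both, beside 1.96 for independent lists and 4.60, or 9.37 and at most 18, in simulation, the 10 leading ones included Scd2, Dhcr7, Fasn, Stard4, Mvd and Lss, genes of lipid and cholesterol metabolism, as well as Sgk1. As deposited 10 genes were lower and 49 higher in both.

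Pairings that share no array gave fewer shared genes than the 24 h pairing. EGTA at 6 h with CD14 deficiency at 24 h shared 1 lower and 4 higher genes, beside 0.78 and 1.28 for independent lists, while 3 genes lower and 5 higher with EGTA went the opposite way with CD14 deficiency. EGTA at 24 h with CD14 deficiency at 6 h shared 5 and 5, beside 1.93 and 0.97, and 9 and 1 went the opposite way. Part of the overlap at matched times may come from the shared wild-type array.

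Across genes, which are not independent replicates, the log2 differences of EGTA and CD14 deficiency correlated with r = 0.16 at 6 h and 0.27 at 24 h. Simulated unchanged groups gave 0.50 at both times. That value follows from giving all simulated arrays equal scatter and sharing 1 of them, so it is no yardstick for the measured r. The covariance was 0.0236 at 6 h, beside 0.0382 simulated, and 0.0612 at 24 h, beside 0.0381 with the 6 h scatter. With the scatter of the 24 h EGTA pair the simulated covariance at 24 h was 0.0576 on average and up to 0.0633, so the measured one lay within that range, while the counts of shared genes lay above theirs. The simulated CD14-deficient array was given the EGTA scatter too. The measured CD14 differences spread wider, with SDs over genes of 0.53 at 6 h and 0.68 at 24 h, beside 0.29 and 0.36 for EGTA. The simulated counts are therefore no upper limit for sharing through the wild-type array alone. Pairings without a shared array gave r of -0.01 and 0.07.

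**Figure D4:**
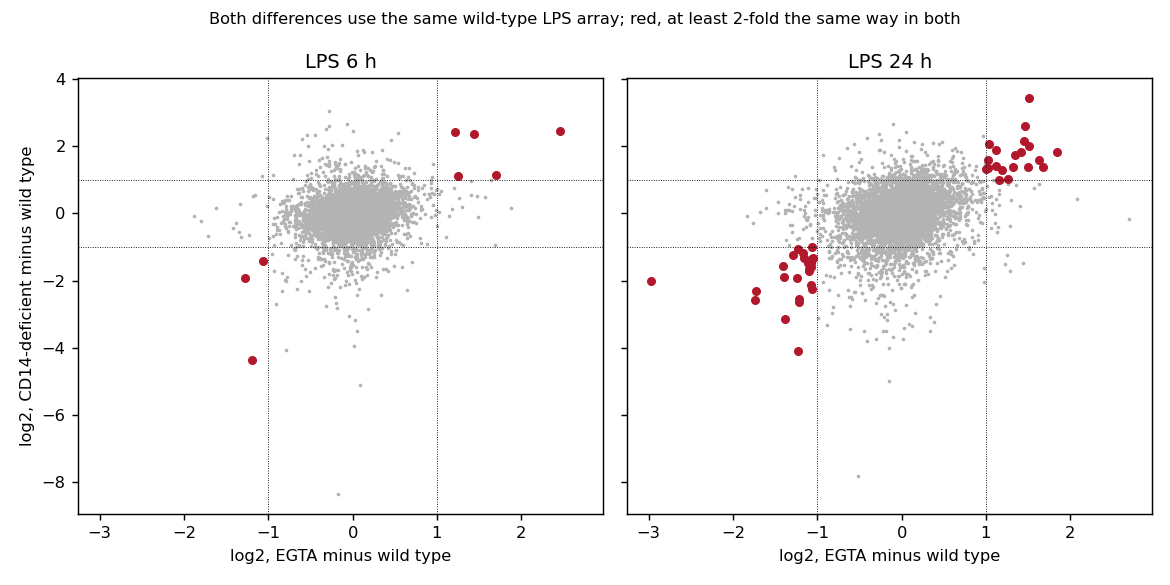
Log2 difference of CD14-deficient minus wild-type (vertical axis) against EGTA minus wild-type (horizontal axis) at 6 h and 24 h of LPS, 1 point per gene, with dotted lines at 2-fold and red points at least 2-fold the same way in both. At 24 h, 24 red genes lie lower and 20 higher, and both axes use the same wild-type array.

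In the additive limma fit, SEs and p-values rest on departure from additivity across times, not on spread between cultures. They do not cover a culture or cohort difference between the genotypes. Averaged over 0, 6 and 24 h, 33 of 7291 genes differed between CD14-deficient and wild-type arrays at an adjusted p below 0.05, 5 higher and 28 lower. The count was 233 as deposited, 79 with an intensity trend and robust variances and 54 with the filter at the 75th percentile. Cd14 was at the floor in every CD14-deficient array and Rpgrip1 at 6 and 24 h, so their fitted values depend on the floor. Rpgrip1 fell by 5.08 ± 0.13 in log2 (SE, adjusted p = 0.00013), Wdfy1, which encodes an adaptor of TLR3 and TLR4 signalling, by 3.45 ± 0.17 (adjusted p = 0.0013) and Cd86 by 3.02 ± 0.16 (adjusted p = 0.0018). The cyclin gene Ccnd2 fell by 2.63 ± 0.17 and Gdf3, a gene of the TGF-beta family, rose by 2.89 ± 0.22. Each lay on the same side at all 3 times, and the genes named here were chosen after their values were seen. No gene passed without the 6 h or without the 24 h arrays, which leaves 1 residual degree of freedom, and 76 passed without the 0 h arrays. The fit called 0 genes for EGTA averaged over 6 and 24 h, with 415 at an unadjusted p below 0.05 and a smallest adjusted p of 0.14, although with intensities as deposited it called 2.

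Markers of other cell types were mostly too dim to compare. No B cell marker reached the level needed in any comparison, and of T and NK cell markers Cd4 alone did. Of the neutrophil markers Lcn2, which macrophages also induce, was at least 46.8-fold higher after 6 h of LPS in CD14-deficient cells, where it lay 4.63-fold above wild type, and S100a8 lay 2.37-fold above it. Mmp8, also on that list, was at the floor there, a log2 difference of -3.25 or lower from unstimulated cells, and stood at -2.88 in wild type. Camp was compared at 24 h alone, at 107 in CD14-deficient cells and 38.6 in wild type. Of dendritic cell markers Fscn1 and Itgax were compared, and neither differed at least 2-fold with EGTA or CD14 deficiency. Single genes stood for the stromal, erythroid and mast cell markers. Dcn was 3.30-fold lower with EGTA at 24 h, Car2 was 13.1-fold higher after 6 h of LPS in wild type, and Kit was 2.01-fold lower there. Macrophage identity genes had medians between -0.28 and 0.11 in all 9 comparisons. Housekeeping genes had medians between -0.36 and 0.22, with Tfrc at -2.09 and Hprt at -1.26 after 24 h of LPS in wild type. The fixed list of neighbours of Cd14 in the genome showed none of 15 at least 2-fold different before LPS, with a median of -0.02. Arap3, outside that list but on the chromosome of Cd14, was at least 2-fold higher in CD14-deficient cells at all 3 times. Of 16 neighbours, 2 had an LPS response at least 2-fold smaller in CD14-deficient cells at 6 h. At 24 h, 1 had a larger and 1 a smaller response there. Xist was present on all 8 arrays, at intensities from 2306 to 4224.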

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

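The LPS responses of 4 named genes ran in opposite directions in the genotypes, each by at least 2-fold, with 1 array per group. Over all compared genes there were 2 of 7090 at 6 h and 4 of 7140 at 24 h, the latter including Phlda3 and Socs2, which the rule for named genes leaves out. None of these differences was tested. Cd74, the invariant chain of class II antigen presentation, stood at -1.06 in log2 in wild type and 1.09 in CD14-deficient cells at 6 h, a difference of 2.15. Its intensities were 2851 and 1367 in wild type and 508 and 1080 in CD14-deficient cells. Vegfa, an angiogenic growth factor gene, stood at 1.20 and -1.42 at 6 h, a difference of -2.62. At 24 h the dendritic maturation marker gene Cd83 stood at 1.39 and -1.33, a difference of -2.72. The spindle assembly gene Tpx2 stood 2.93 higher after LPS in wild type, while its intensity was 376 before and 188 after LPS in CD14-deficient cells, a difference of -3.94.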

How the results depend on the processing

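Quantile normalization against deposited intensities made the largest change of any setting tried for the EGTA comparison at 6 h. Of 192 alternative values of counts, 122 lay within 1.5 times the reported one. All 24 counts with a floor at the 20th percentile, all 18 with no floor and all 18 with equal medians did so. Of 4235 alternative values of named genes none that differed at least 2-fold changed sign, and 703 moved by over 0.29 in log2, the SD over genes of the EGTA difference at 6 h, which stands in for the absent replicate spread. Of 630 alternative values of list medians outside the central 95% of random lists, 3 changed sign and 79 moved. With intensities as deposited, the medians with EGTA at 6 h were -0.11 for endoplasmic reticulum stress genes and -0.58 for apoptosis regulators, beside -0.78 for all genes. With the mean of all probe sets, immediate early genes with EGTA at 24 h stood at -0.031. The cause of the last was not tested.

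With intensities as deposited, genes higher and lower numbered 365 and 2199 for LPS in wild type at 24 h, 2 and 1353 for EGTA at 6 h, 115 and 42 for EGTA at 24 h, 99 and 447 for CD14 deficiency at 6 h and 1089 and 215 at 24 h, and 1412 were lower for LPS in CD14-deficient cells at 6 h. Genes lower and higher in both conditions numbered 133 and 1 at 6 h and 10 and 49 at 24 h. The additive fit called 233 genes for CD14 deficiency and 2 for EGTA. The smallest adjusted p there, 1.5e-115, is no measure of strength, and its cause was not tested. The trimmed means differ 1.68-fold between arrays.

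With the filter at the 75th percentile, which leaves fewer genes, higher and lower numbered 480 and 326 for LPS in wild type at 6 h, 455 and 362 at 24 h, 11 and 2 for EGTA at 6 h, 25 and 20 at 24 h, 94 and 123 for CD14 deficiency at 6 h and 154 and 227 at 24 h. There 42 were higher for CD14 deficiency before LPS, and 341 and 310 lower for LPS in CD14-deficient cells at 6 and 24 h. Shared lower and higher genes numbered 1 and 1 at 6 h and 7 and 9 at 24 h, and the additive fit called 54 for CD14 deficiency. With a 3-fold threshold, which is stricter by construction, higher and lower numbered 381 and 185, then 345 and 244, for LPS in wild type at 6 and 24 h; 408 and 203, then 329 and 277, in CD14-deficient cells; 6 and 4, then 8 and 8, for EGTA; and 13 and 111, 47 and 76, and 77 and 152 for CD14 deficiency at 0, 6 and 24 h. Shared lower and higher genes then numbered 0 and 1 at 6 h and 3 and 2 at 24 h. With no filter, 9 genes were higher in both at 6 h. With the mean of probe sets, 11 were lower with EGTA at 6 h. With no shared array, EGTA at 6 h shared 1 lower gene with CD14 deficiency at 24 h, and EGTA at 24 h shared 5 lower and 5 higher with CD14 deficiency at 6 h. Shared lower genes that LPS induced numbered 0 at 6 h and 6 at 24 h, against 2 and 15, when induction was required in the CD14-deficient and the EGTA arrays in place of the wild-type LPS array, a stricter demand by construction. With the scatter of the 24 h EGTA pair, chosen after seeing the data, simulated unchanged groups shared 9.69 lower and 9.37 higher genes at 24 h in place of 4.55 and 4.60, and the simulated covariance was 0.0576 in place of 0.0381; that pair may hold true differences, which would raise these values. The intensity trend with robust variances called 79 genes for CD14 deficiency, and leaving out a time called between 0 and 76. The cause of these last shifts was not tested, apart from the 1 residual degree of freedom left without 6 h or 24 h. With the unstimulated CD14-deficient array as the baseline, chosen after seeing the data, LPS in wild type gave 863 higher and 846 lower at 6 h and 935 and 1045 at 24 h. Low signal limits the dimmest genes, since 40% of all values lie at the floor. No paired analysis of replicates was possible because each group has 1 array, and the additive fit matches arrays by time.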

Other observations

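The tests of explanations in this part were all chosen after the results they bear on had been seen. Several gene groups not described above also stood apart. Metal-responsive genes were at least 2-fold higher in 6 of 10 and lower in 2, Slc40a1 and Hmox1, after 6 h of LPS in wild type, with Slc30a4, a zinc transporter gene, 3.33 higher in log2 and Mt2 8.22-fold higher, and had a median of 0.04 at 24 h. Adhesion and matrix genes were higher in 7 of 19 at 6 h in wild type, with Timp1 11.3-fold higher and the matrix protease gene Mmp14 8.77-fold, and Mmp14 was at least 46.7-fold higher in CD14-deficient cells at that time. Apoptosis regulators were higher in 6 of 15 at both times in wild type, led by the death receptor gene Fas (16.9-fold at 6 h), while Gadd45a stood at -3.53 and -3.02 in log2. LPS receptor and signalling genes were higher in 5 of 13 at 6 h, while Irak1, chosen after its value was seen, stood at -1.05. With EGTA at 24 h, 1 of the 10 metal-responsive genes, Slc40a1, was at least 2-fold higher, and Mt1 and Mt2 were lower.

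In CD14-deficient against wild-type cells, LXR and lipid efflux genes had medians of 0.35, 0.27 and 0.36 at 0, 6 and 24 h, above 99% or more of random lists each time, with 3 of 10 at least 2-fold higher at 6 h. Alternative activation genes were lower in 2 of 5 at 24 h, Ccl22 and Ccl17. Prostanoid synthesis genes had a median of -0.26 with EGTA at 6 h and none of 11 differed at least 2-fold. NFAT pathway components showed none of 11 at least 2-fold different with EGTA at 6 h and none of 10 at 24 h.

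Normalization does not account for the lower interferon genes in unstimulated CD14-deficient cells, since their median was -3.70 under the scaling nearest 0. Wild-type cells already stimulated with LPS and mixed into the unstimulated sample would raise interferon and inflammatory genes by the same fraction of their rise to the 6 h LPS level. Rises were taken over the unstimulated CD14-deficient array, which stands in for unmixed wild-type cells. Only genes well above that baseline after LPS were used, 28 interferon and 17 inflammatory ones at 6 h. Ccl2, Ccl3, Ccl4 and Ccl7, high before LPS in both genotypes, were left out. The fractions had a median of 0.19 (quartiles 0.085 to 0.44) in the interferon list and 0.040 (0.013 to 0.074) in the inflammatory list. Against the 24 h array the medians were 0.21 and 0.045. For the genes used, this argues against mixing as the only source. A culture or cohort difference unrelated to CD14 and an effect of CD14 itself cannot be told apart, since there is 1 unstimulated array per genotype.

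The higher endoplasmic reticulum stress genes with EGTA at 6 h and cholesterol genes at 24 h are the second pattern. With the CD14-deficient LPS array as baseline in place of the wild-type one, the stress list stayed at 0.54, above all 10000 random lists, so the wild-type 6 h array is not the whole source. As deposited its median was -0.11, with 0 of 21 genes at least 2-fold higher and 1 lower, so the higher level rests on normalization. It still lay 0.67 above the median of all genes there, again above all random lists. Scaling a whole array moves the list and the random lists alike, so this placing shows only a standing relative to other genes. The cholesterol list fell to 0.11 with the CD14-deficient 24 h array as baseline, above 8129 of 10000 random lists, so the wild-type 24 h array may itself stand low, or both conditions may raise these genes. The list was also higher in CD14-deficient cells in pairs without that array, with medians of 0.59 at 0 h and 0.45 at 6 h (0.12 as deposited), though none of the 14 genes reached 2-fold at either time.

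Genes set apart by CD14 deficiency at all times, 33 in the additive fit, are the third pattern. The other 9 splits of the 6 arrays into groups of 3 called at most 1 gene. Most of them put both arrays of a time in 1 group, and all leave part of any genotype difference in the residual spread. Low counts were thus favoured there, and the splits cannot decide on chance. In number, too, 10 splits are too few for a share below 0.05. Donor-strain DNA carried along with the deleted locus could cluster the called genes, and 7 lay on 1 chromosome, not that of Cd14. On the chromosome of Cd14 lay 3, namely Cd14, Arap3 and Esco1. How close Arap3 and Esco1 lie to Cd14 was not tested, so donor DNA around Cd14 stays open for them. As many as 7 on 1 chromosome came up in 6.18% of 10000 random sets, a share whose reading was settled after it had been seen. The 7 spread over 209 of the 243 genes tested there, which argues against 1 short segment holding all 7 and leaves several open. That span is set by the first and the last called gene alone, and grouping within it was not tested. A sequence difference under 1 probe set does not explain most of the testable genes. Of the 10 with another bright probe set, 8, or 80%, had at least 1 such set at least 2-fold off in the same direction. Esco1 and Ngdn were the exceptions. Where a gene had several other sets, 1 was enough, and for Ccnd2 another set stood at -0.91. The other genes have no second probe set to test, and an effect of CD14 loss stays open.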
